A study of Mus musculus with 11 samples.

How the data were processed

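PolyA RNA was measured in single cells of 11 mouse samples, 8 stem cell libraries and 3 libraries of fetus, placenta and yolk sac, each group with 1 library. Per the labels' protocols, libraries were made with the Chromium Next GEM Chip G kit of 10x Genomics. Per the submitters' processing notes, FastQC 0.11.9, Trim Galore 0.6.5 and STAR 2.7.6a were used with the mouse genome build mm10, with no role or order stated, and the UMI counter and gene annotation are not named. The authors deposited 3 matrices of raw UMI counts per gene and cell, as whole numbers with no normalization, each with its cell barcodes and gene symbols. Total counts and numbers of genes listed beside the deposited barcodes were checked and equal those of the matrices for every cell. The library of each cell was taken from the name joined to its barcode. The stem cell tables list 38481 features, of which 37053 symbols match the mouse annotation, and 27041 of 27848 symbols match in the embryo table. The files hold symbols and no identifiers, so no coordinates are given.

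Cells with at least 500 genes and at most 20% of UMIs from mitochondrial genes were kept, and this removed no deposited cell. Lowest genes and highest UMIs per cell differ between libraries, as the deposited files show. UMIs were summed per library over all kept cells and scaled to CPM. The log2 fold of a gene is that of CPM plus 1 in a pair of libraries. Exact Poisson 95% intervals are given for levels, and exact binomial 95% intervals (Clopper-Pearson) for shares, both for counting error only. A level of 20 CPM had an interval from 18.9 to 21.2 in the stem cell library with the fewest UMIs, induced EpiLC day 4, and from 19.2 to 20.8 in EpiLC, which had the most. A gene at 0 UMIs was given a floor of 3 UMIs, and a fold against it is a lower bound.

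Comparisons were EpiLC against ESC, each induced EpiLC day against EpiLC and against the day before, induced EpiLC day 4 against ESC, later mCMG days against day 1, and mCMG against induced EpiLC at matched days. No test was made between libraries. The comparisons, filters, 26 gene lists and cell type markers and the rule for naming genes were set before the data were examined. Per comparison the rule names the 8 highest and 8 lowest folds among genes with at least 20 CPM in 1 of the libraries, without mitochondrial and ribosomal protein genes, and up to 4 genes of each described list, 2 by fold and the others by level. The lists described were chosen after their values were seen, and so were GFP, the genes set out in trophoblast-like cells and the genes named for one comparison and given in another. A list gene was measured with at least 10 UMIs in both libraries together and counted at a fold of 2 or more. The median fold of each list was placed among 10000 random lists of equal size matched on expression in 20 bins.

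For shares of cells, each cell with at least 10000 UMIs was thinned to that number, the depth that 80% of the cells of each stem cell library reach. A cell was counted with at least 1 Zscan4 family UMI, with UMIs of at least 3 genes of the 2-cell list, or with a GFP UMI. Cells were clustered per table with scanpy 1.11.5 on log values of counts per 10000, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with igraph 0.11.9. A cluster was named after a class with at least 3 markers raised, a median log2 fold of at least 1 and a lead of at least 0.5 over the next class. These limits, and the merging of visceral endoderm and hepatocyte classes, were set after clusters had been seen. Clustering was repeated with other random seeds and with components rounded to 3 or 4 decimals, 42 times in all.

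Within each of the 6 induced libraries, cells with at least 3 genes of the 2-cell list were set against cells with none, and the mean over libraries was tested with an exact two-sided sign-flip test, adjusted by Benjamini-Hochberg over 24 measures. These contrasts were added after the data were seen. The cells were thinned to equal depth to choose them, and levels were summed over all their UMIs. Genes that separate library sets were looked at again in cells of 20000 to 30000 UMIs of each stem cell library, 106 cells or more per library.

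The steps were tested on simulated data for induced EpiLC day 4 against EpiLC over 24003 genes, with 50 genes changed per fold size. This was done after the real steps had first been run. The first criterion, at least 70% of genes within 0.1 log2 of the true fold, failed at 8-fold, where 66% were within it, because the added 1 CPM shrinks folds of genes that fall to low levels. Among genes simulated as lower, 84% were within 0.1 at 2.5-fold, 56% at 4-fold and 32% at 8-fold, so large decreases are understated. Against the fold expected with the added CPM, 94% or more were within 0.1, a criterion set after the failure. All genes changed by 2.5-fold, 4-fold or 8-fold were counted at 2-fold or more, against 0 of those changed 1.5-fold and 0 of 5552 unchanged genes. Of 200 random lists of 20 genes, 3.5% fell under percentile 5 and 2% over percentile 95. Both simulated libraries were drawn from the EpiLC profile with Poisson error alone, without variation between libraries or cells. The 0 calls among unchanged genes and the list shares follow from that design and cannot show how often real libraries differ without cause. Changed genes had at least 20 CPM in EpiLC, so genes that start at lower levels were not tested.

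Alternatives were TMM scaling (edgeR 4.0.16) and DESeq2 1.42.0 size factors in R 4.3.3, the mean of each cell's own CPM, a pseudocount of 0.1, other filters on cells and genes, removal of doublets called by Scrublet, other thinning depths and other clustering settings. TMM moved the median of all genes by −0.15 on the log2 scale in induced EpiLC day 1 against EpiLC, and DESeq2 by −0.13 in mCMG against induced EpiLC day 2. Scrublet called 1 cell in induced EpiLC day 1 and 0 cells in the mCMG libraries, so it is no guide to doublets there. Differential expression tests, trajectories and imprinting by allele were left out, since each group has 1 library and the tables hold no alleles. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.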

Results

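PolyA RNA of single mouse cells was counted in 11 libraries made with 10x Genomics droplet chemistry, 1 library per group. The 8 stem cell libraries held embryonic stem cells (ESC) kept in 2i/LIF, epiblast-like cells (EpiLC) made from ESC with FGF2 and Activin A, EpiLC on days 1, 2 and 4 of chemical induction, and cells labelled mCMG on days 1, 2 and 4. The labels do not spell out mCMG. The labels of induced EpiLC day 1 and the mCMG libraries list an induction with the cytokine LIF, the growth factor BMP4, sodium D-lactate, NaB and A366, an inhibitor of the histone methyltransferases EHMT1 and EHMT2. The 3 other libraries held fetus, placenta and yolk sac of embryos that carried a red fluorescent protein and a green one (GFP) driven by MuERVL, an endogenous retrovirus active at the 2-cell stage. The cells were purified by flow cytometry per the labels, which do not state the gate.

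The ESC library held 3202 cells and 96164570 unique molecular identifiers (UMIs), and the EpiLC library 3587 cells and 127317635 UMIs. Induced EpiLC day 1 held 6180 cells and 85408867 UMIs, day 2 held 2791 cells and 124478552 UMIs, and day 4 held 1319 cells and 61203522 UMIs. The mCMG libraries held 6699 cells and 116024320 UMIs on day 1, 7159 cells and 110537026 UMIs on day 2, and 2921 cells and 99372012 UMIs on day 4. Fetus held 4877 cells and 54140669 UMIs, placenta 697 cells and 12654867 UMIs, and yolk sac 3039 cells and 49853270 UMIs. The median UMIs per cell ran from 13138 in induced EpiLC day 1 to 46085 in induced EpiLC day 4 among the stem cell libraries, and from 10342 to 13428 among fetus, placenta and yolk sac. With 1 library per group no difference between groups could be tested, and the 95% intervals given here (exact Poisson for levels, exact binomial for shares) cover counting error only. The libraries of induced EpiLC day 1, mCMG day 1 and mCMG day 2 held cells with as few as 2000 genes and at most 39989 UMIs, while the other 5 stem cell libraries started at 3001 genes and reached 99641 UMIs. Expression levels are CPM, a gene's UMIs scaled to equal totals per library, and folds are log2 with 1 CPM added. A list's floor median is the median of its folds without the added CPM and with genes at 0 UMIs set to 3 UMIs.

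How EpiLC stood relative to ESC before induction was read from EpiLC against ESC. EpiLC held less RNA of naive pluripotency genes, which mark the pre-implantation epiblast, and more RNA of formative, germline and trophoblast genes. Of 20 naive genes 11 were at least 2-fold lower and 1 was higher, with a median log2 fold of −1.35 (floor median −1.37). Tfcp2l1 stood at 326 CPM in ESC and 29.3 in EpiLC (−3.43), Klf2 at 451 and 52.3 (−3.08), and Zfp42 at 786 and 246 (−1.67), while Dppa5a was alike at 4511 and 4749.7 (0.07). Of 20 formative or primed genes 13 were at least 2-fold higher and 0 lower (median 1.65, floor median 1.93). Pou3f1, a transcription factor of the post-implantation epiblast, stood at 0.686 CPM in ESC and 47.2 in EpiLC (4.84), and Tcf15 at 10.3 and 88.0 (2.97). Fgf5 had 1 UMI in ESC and 8.88 CPM in EpiLC, a ratio of 853 with an interval from 153 to 33741. Dnmt3b was alike at 93.85 CPM in ESC and 85.4 in EpiLC (−0.13). Clusters were named against all other cells of the same table. By that measure 0 of 3587 EpiLC cells lay in a cluster named formative or primed, against 4198 of 6180 in induced EpiLC day 1. Of 25 germline genes that somatic cells silence, 18 were higher and 0 lower (median 2.44, floor median 2.75), among them Taf7l (2.21 and 112 CPM, 5.14), Slc25a31 (3.48 and 90.2, 4.35) and Sycp1 (1.15 and 45.5, 4.43). Targets of LIF and STAT3 were lower for 9 of 12 genes and higher for 0, including Sp5 (34.8 and 0.801 CPM, −4.31) and Klf4 (241 and 40.7, −2.53). Trophoblast genes were higher for 12 of 22 and lower for 3, with Krt18 at 4.85 and 77.8 CPM (3.75) and Peg10 at 7.88 and 114 (3.70). The folds furthest below 0 included the surface proteins Ly6a (449 and 3.47 CPM, −6.65) and Ifitm1 (1020.5 and 26.2, −5.23) and the hormone precursor Trh (308 and 5.58, −5.55). The medians of the naive list and of the LIF and STAT3 targets lay at percentile 0 among 10000 random lists matched on expression, and those of the formative, germline and trophoblast lists at percentile 100. Of 22 genes of the 2-cell stage 0 were at least 2-fold higher and 2 were lower, among them Gm5039 (3.42 and 0.668 CPM, −1.41).

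Induced EpiLC on days 1, 2 and 4 against EpiLC address how RNA levels stood as the chemical induction went on. Transcripts of the 2-cell stage, when the mouse embryo switches on its own genome, were far higher in induced EpiLC on days 1 and 2, and by day 4 lay closer to the EpiLC level. On day 1, 40 of 44 genes of that list were at least 2-fold higher and 0 lower, with a median log2 fold of 4.59 and a floor median of 9.06. Day 2 had 39 higher (median 4.14, floor median 8.45), and day 4 had 22 of 38 higher (median 1.70, floor median 5.26), a count that was 36 with a pseudocount of 0.1 CPM and 11 with a minimum of 5 CPM. Gm8300 stood at 0.660 CPM in EpiLC, 893 on day 1 (9.07), 706 on day 2 (8.73) and 93.1 on day 4 (5.83). Gm21761 stood at 0.699 CPM in EpiLC, 2073 on day 1 (10.25), 727 on day 2 and 54.4 on day 4, and the long non-coding RNA Platr31 at 2.42, 3233, 1541 and 167. A transcript named GFP in the tables stood at 2.90 CPM in EpiLC, 199 on day 1, 189.7 on day 2 and 41.7 on day 4, although the label of the day 1 cells gives a wild-type genotype. Each of these 3 medians lay at percentile 100 among 10000 matched random lists. Against day 1, day 2 had 1 gene of the 2-cell list higher and 8 lower, 9 formative or primed genes lower and 0 higher, such as Pou3f1 (630.1 and 87.8 CPM), and 5 of 22 trophoblast genes higher and 1 lower, such as Krt8 (13.6 and 83.1 CPM). Against day 2, day 4 had 36 genes of the 2-cell list lower and 0 higher (median −2.72, floor median −3.35).

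On day 1 several formative and early neural genes also stood higher in induced EpiLC than in EpiLC. Pou3f1 stood at 47.2 CPM in EpiLC and 630.1 on day 1 (3.71), and Dnmt3b, which writes new DNA methylation, at 85.4 and 483. Of 20 formative or primed genes 8 were higher on day 1 and 1 lower (median 0.52, floor median 0.54, percentile 99.2 among matched random lists), and of 15 neuroectoderm genes 9 were higher and 0 lower (floor median 2.47), such as Crabp1 (2.44 and 35.3 CPM, 3.40). Id1 and Id3, direct targets of BMP signalling, stood at 5.35 and 350 CPM and at 3.73 and 140, and 4 of 12 BMP targets were higher and 1 lower. Subunits of oxidative phosphorylation were lower for 7 of 18 genes, including Ndufb8 (445 and 135 CPM, −1.72), and higher for 1, Ndufa4 (791 and 1723 CPM, 1.12). Germline genes were lower for 9 of 25 and higher for 1 (median −0.79), with Hormad1 at 155 CPM in EpiLC and 26.2 on day 1. Id1 also belongs to 108 genes that separate the libraries of induced EpiLC day 1, mCMG day 1 and mCMG day 2 from the other 5, so its level follows the deposited limits as well as the day.

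By day 4 induced EpiLC had more naive and trophoblast RNA than EpiLC and less formative RNA. Of 20 naive genes 11 were at least 2-fold higher and 2 lower (median 1.23, floor median 1.27), with Tbx3 at 25.5 CPM in EpiLC and 201 on day 4 (2.93) and Zfp42 at 246 and 1381 (2.48). Of the formative or primed genes 0 were higher and 10 lower (median −0.98, floor median −1.24), with Lef1 at 21.6 and 0.458 CPM (−3.95) and Fgf5 at 8.88 and 0.0327 (−3.26). LIF and STAT3 targets were higher for 6 genes and lower for 0, led by Socs3 (3.13 and 37.8 CPM, 3.23) and Klf4 (40.7 and 172, 2.05). The Nodal pathway genes Lefty1 (403 and 1.23 CPM, −7.51) and Lefty2 (80.4 and 3.45, −4.19) were among the folds furthest below 0. Of 23 trophoblast genes 13 were higher and 0 lower (median 1.32, floor median 1.84), among them Plac1 (0.353 and 46.9 CPM, 5.14), Krt7 (2.19 and 35.6, 3.52) and Krt8 (54.2 and 316, 2.52). The imprinted genes H19 (0.911 and 659 CPM, 8.43) and Cdkn1c (19.4 and 226, 3.48) were also higher. Without 113 trophoblast-like cells told by their own transcripts, 5 trophoblast genes were higher in place of 13, and the folds of Krt7, Krt8 and Cdkn1c changed sign, to −0.066, −1.54 and −0.79. H19 stayed above EpiLC without them, at 141 CPM. In 5 of 42 clusterings the group held 79 cells, and without those 7 trophoblast genes were higher, Krt7 kept a fold of 1.23, and Krt8 and Cdkn1c stood at −0.63 and −0.067. Germline genes were lower for 11 of 25 and higher for 3, among them Dazl, an RNA-binding protein of germ cells, at 49.6 CPM in EpiLC and 133 on day 4 (1.41).

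**Figure D1:**
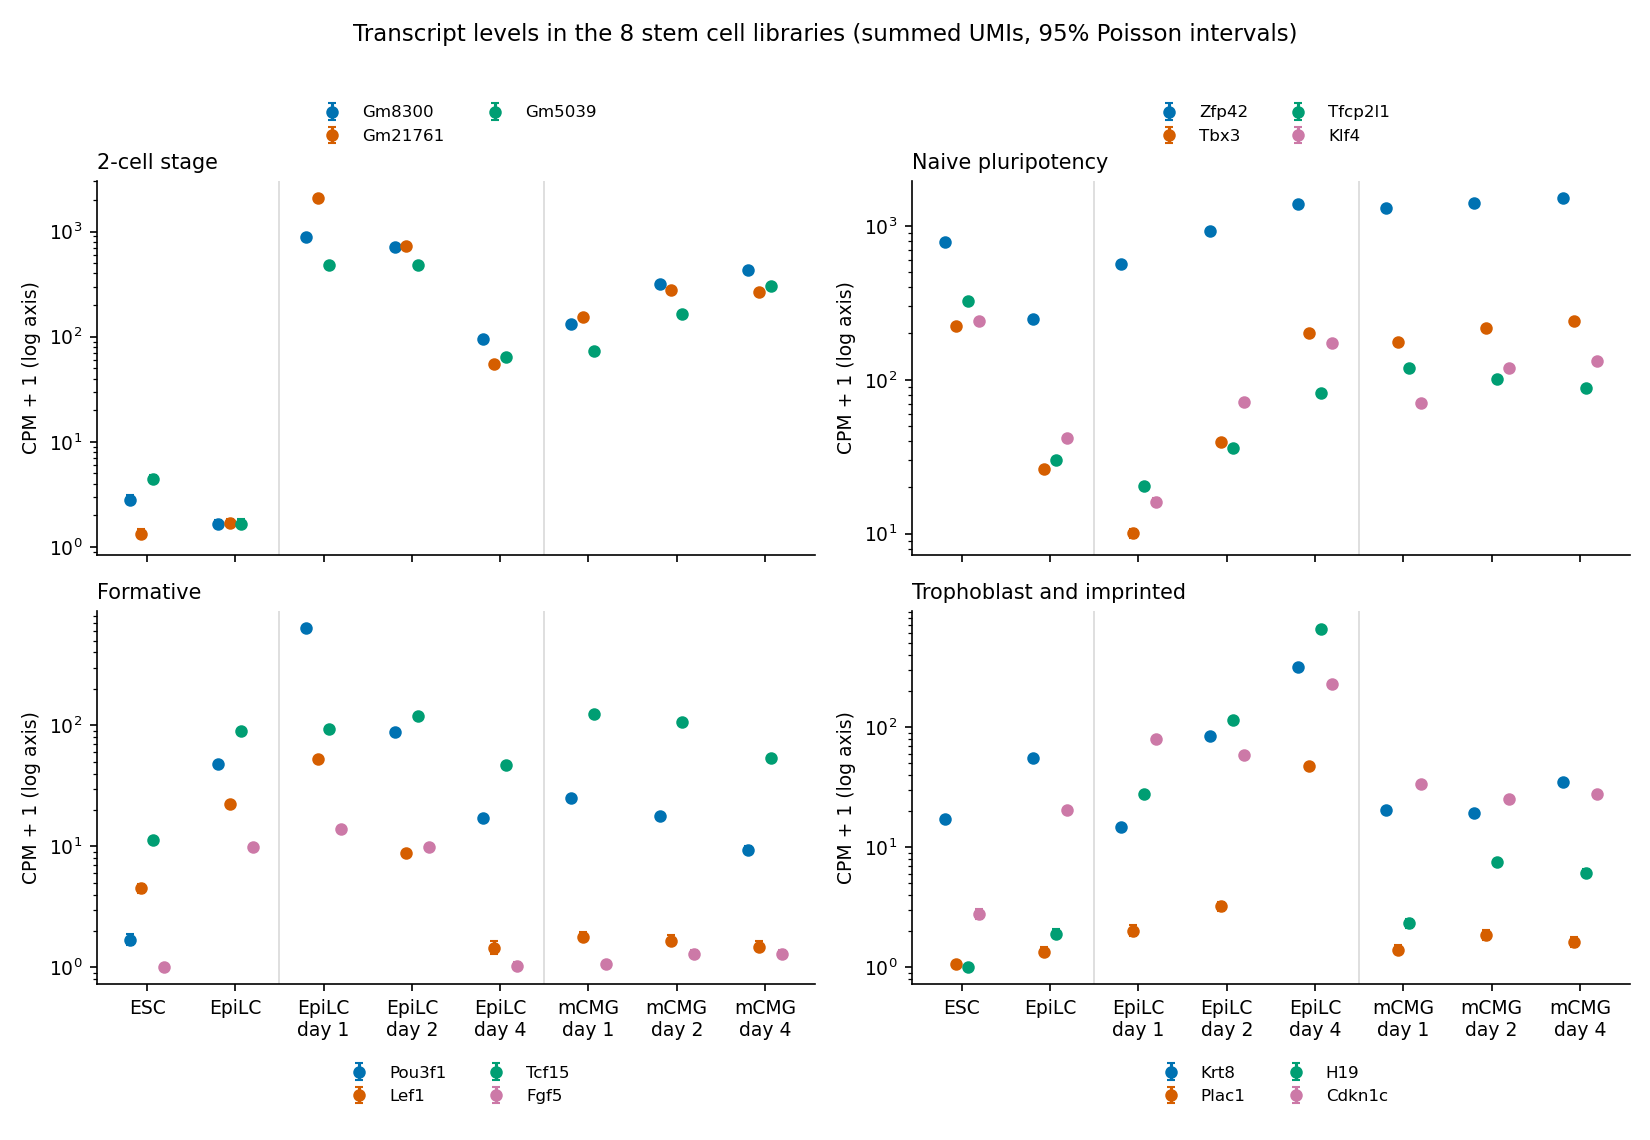
Levels of genes in the 8 stem cell libraries, in CPM plus 1 on a log axis, by library along the horizontal axis, with bars for 95% Poisson intervals of counting error; panels hold genes of the 2-cell stage, naive, formative and trophoblast or imprinted genes. Gm8300 stood at 893 CPM in induced EpiLC day 1 and 93.1 on day 4, while Krt8 stood at 316 CPM on day 4 and 33.8 in mCMG day 4.

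Whether induced cells returned to the state of the ESC they first came from was addressed by induced EpiLC day 4 against ESC. On day 4 the naive genes Zfp42 and Klf4 lay within 2-fold of their ESC levels, after lower levels in EpiLC, while many trophoblast and 2-cell transcripts stood higher than in ESC. The log2 fold was 0.81 for Zfp42 and −0.48 for Klf4, whereas Tfcp2l1 stood at 326 CPM in ESC and 81.6 on day 4 (−1.99), and 0 naive genes were at least 2-fold higher and 5 lower. Of 23 trophoblast genes 18 were higher and 2 lower (median 3.14, floor median 4.15), including Peg10 (7.88 and 509.5 CPM, 5.85) and Krt18 (4.85 and 211, 5.18), and 9 were higher without the 113 trophoblast-like cells, or 14 without the 79 cells of the smallest such group. Imprinted genes went both ways, with 9 of 20 higher and 5 lower. H19, a maternally expressed RNA, had 0 UMIs in ESC and 659 CPM on day 4, at least 21117-fold higher, and Phlda2 stood at 3.92 and 193 CPM (5.30), whereas Kcnq1ot1 stood at 590.4 and 265 (−1.15). The 113 trophoblast-like cells held 80.7% of the day 4 UMIs of H19 and 94.5% of those of Phlda2. In the other day 4 cells H19 stood at 141 CPM, Phlda2 at 11.7 and Kcnq1ot1 at 239. Genes of the 2-cell stage were higher for 21 of 38 and lower for 0 (median 1.56, floor median 5.21), such as Gm21761 (0.333 and 54.4 CPM, 5.38). Germline genes were higher for 14 and lower for 0 (median 1.59, floor median 2.07), with Tuba3b at 1.22 and 25.3 CPM (3.57). Targets of FGF and ERK signalling, which 2i blocks, were higher for 10 of 15 (median 1.37, floor median 1.83) and lower for 1, Egr1 (58.2 and 22.7 CPM, −1.32), those higher including Phlda1 (3.75 and 32.6 CPM, 2.82) and Myc (1.17 and 11.2). LIF and STAT3 targets were higher for 0 and lower for 6, with Sp5 at 34.8 and 0.654 CPM (−4.44). Stress response genes were higher for 8 of 17 and lower for 0, such as Chac1 (0.988 and 12.7 CPM, 2.79). Trh, at 308 CPM in ESC and 7.48 on day 4 (−5.19), was also low in EpiLC at 5.58.

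How mCMG cells stood on later days of induction was read against their own day 1. Transcripts of the 2-cell stage were higher on days 2 and 4 than on day 1, the opposite order to induced EpiLC. On day 2, 15 of 42 genes of that list were at least 2-fold higher and 0 lower (median 0.75, floor median 1.12), and on day 4, 22 of 44 were higher and 0 lower (median 0.94, floor median 1.56). Gm8300 stood at 130 CPM on day 1 and 426 on day 4 (1.70), Gm5039 at 72.8 and 300.4 (2.03), and Usp17la at 8.15 and 75.9 (3.07). Dppa3, a maternal factor that guards DNA methylation, stood at 19.3 CPM on day 1 and 89.98 on day 2 (2.16). GFP stood at 54.2, 166 and 239 CPM on days 1, 2 and 4, with a wild-type genotype on the labels. Germline genes were higher on day 4 for 8 and lower for 1, among them Tuba3b (10.7 and 96.8 CPM, 3.07), and targets of FGF and ERK signalling were higher for 0 and lower for 6, among them Egr1 (153 and 19.5, −2.92) and Myc (20.6 and 3.89). The folds furthest from 0 also included Reg1 (4.75 and 142 CPM, 4.64) and the calcium-binding protein Anxa2 (61.2 and 5.24, −3.32). Naive genes went both ways, with 2 of 20 at least 2-fold higher on day 4 and 4 lower, and Zfp42 stood at 1303 and 1507 CPM. Pou5f1 (588 and 87.5 CPM, −2.74) and Slc7a5 (177 and 20.4, −3.06) are among the 108 genes that separate the library sets, and the day 1 and day 4 libraries lie in different sets.

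At matched days, mCMG against induced EpiLC addresses how the course of induction differed between cells with different labels. On day 1 mCMG held fewer 2-cell and formative transcripts and more naive ones, and by day 4 the order of the 2-cell genes had turned round. Genes of the 2-cell stage were lower in mCMG for 38 on day 1 (median −2.70, floor median −3.24) and 32 on day 2 (median −1.40, floor median −1.90), and higher for 28 of 43 on day 4 (median 1.73, floor median 2.13). Gm8300 stood at 893 CPM in induced EpiLC and 130 in mCMG on day 1 (−2.77), and at 93.1 and 426 on day 4 (2.18), where Tcstv3 stood at 3.73 and 25.0 (2.46) and Zscan4a at 0.752 and 8.44 (2.43). Dppa3 stood at 517 and 19.3 CPM on day 1 (−4.67) and at 825 and 89.98 on day 2 (−3.18). Trophoblast genes were lower in mCMG for 8 of 22 on day 2 and higher for 2, with Krt8 at 83.1 CPM in induced EpiLC and 18.2 in mCMG (−2.13). The day 2 libraries also differ in the deposited limits, with a median of 43401 UMIs per cell in induced EpiLC and 14463 in mCMG. On day 1, 14 naive genes were higher and 1 lower in mCMG (median 1.21, floor median 1.27), with Tbx3 at 9.06 and 175 CPM (4.13), and 12 formative or primed genes were lower and 1 higher (median −1.18, floor median −1.47), with Pou3f1 at 630.1 and 24.2 CPM (−4.65) and Lef1 at 52.0 and 0.802 (−4.88). On day 4, 16 of 23 trophoblast genes were lower in mCMG and 0 higher (median −2.01, floor median −2.64), including Plac1 (46.9 and 0.624 CPM, −4.88) and Krt8 (316 and 33.8, −3.18), and H19 stood at 659 and 5.16 (−6.74). Without the 113 trophoblast-like day 4 cells 4 trophoblast genes were lower in place of 16 (7 without the smallest group of 79 cells), the Krt8 fold was 0.87 and that of Ldoc1 was 0.16, against −3.18 and −3.58 with them. H19 in induced EpiLC day 4 stood at 141 CPM without the 113 cells, still above mCMG. Lefty2, a Nodal inhibitor, stood at 3.45 CPM in induced EpiLC day 4 and 43.5 in mCMG day 4 (3.32).

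How many cells carried 2-cell transcripts was read as shares of cells thinned to 10000 UMIs, since depth per cell differed between libraries. Cells under that depth were left out, 1224 of 6180 in induced EpiLC day 1 and 937 of 7159 in mCMG day 2. Induced EpiLC day 2 lost 3 cells. Among thinned cells, those with 2-cell list genes had fewer UMIs than those without, so the cut may remove such cells unevenly. Thinning to 1000 UMIs left out 0 cells, and its shares are given with the other settings. Zscan4 family genes, which mark 2-cell-like cells, had at least 1 UMI in 29.6% of induced EpiLC day 1 cells (28.3 to 30.9), 22.7% of day 2 cells (21.1 to 24.3) and 3.43% of day 4 cells (2.51 to 4.56). In mCMG the share was 4.48% on day 1 (3.98 to 5.02), 10.2% on day 2 (9.49 to 11.0) and 14.5% on day 4 (13.3 to 15.9). In the uninduced ESC and EpiLC the share was 0.0323% and 0.0282%, which gives no measure of free RNA in libraries where these transcripts are abundant. Within induced EpiLC day 4, 0 of 113 trophoblast-like cells had a Zscan4 UMI (0 to 3.21), against 3.75% of the other 1199 cells (2.75 to 4.99), with overlapping intervals, at median depths of 55391 and 45563 UMIs before thinning. Cells with at least 3 genes of the 2-cell list made up 1.77% of the trophoblast-like cells (0.215 to 6.25) and 10.7% of the others (8.98 to 12.6). GFP had a UMI in 1.77% (0.215 to 6.25) and 13.8% (11.9 to 15.9), and for both measures the intervals lay apart. These values argue against free RNA spread evenly over day 4 cells as the only source there, though the groups were made on expression. The size of the part due to free RNA was not measured in any induced library. At least 2 UMIs were found in 19.8%, 16.2% and 2.06% of induced EpiLC cells on days 1, 2 and 4 and in 2.68%, 5.87% and 9.49% of mCMG cells. Clusters named 2-cell-like held 31.3%, 21.0% and 1.67% of induced EpiLC on days 1, 2 and 4. They held 3.55%, 11.5% (10.8 to 12.3) and 9.38% (8.35 to 10.5) of mCMG, so by that measure mCMG day 4 lay below day 2. Clusters were named against the other cells of their own table, and the mCMG table holds no uninduced cells. Cluster shares of induced EpiLC and mCMG are therefore not on the same scale. They rest on 1 clustering, and their change with other seeds was not measured. Cells with at least 3 genes of the 2-cell list made up 64.1%, 44.3% and 9.91% of induced EpiLC on days 1, 2 and 4, 6.99%, 23.4% and 39.8% of mCMG, and 0.129% of ESC and 0.113% of EpiLC. GFP had a UMI in 26.7%, 26.9% and 12.8% of induced EpiLC cells and in 8.52%, 25.5% and 41.6% of mCMG cells, against 0.873% in ESC and 2.03% in EpiLC. The gate used to purify the cells, which the labels do not state, can set each of these shares. Without thinning the Zscan4 share was 34.6% on induced EpiLC day 1 and 37.8% on day 2, and cells with at least 3 genes made up 75.5%, 91.0% and 34.3% of induced EpiLC on days 1, 2 and 4 and 14.0%, 37.0% and 77.5% of mCMG, so for both measures the order of induced EpiLC days 1 and 2 turned when cells were compared at unequal depth. GFP shares without thinning were 31.4%, 41.1% and 21.5% in induced EpiLC and 11.8%, 31.5% and 62.1% in mCMG.

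**Figure D2:**
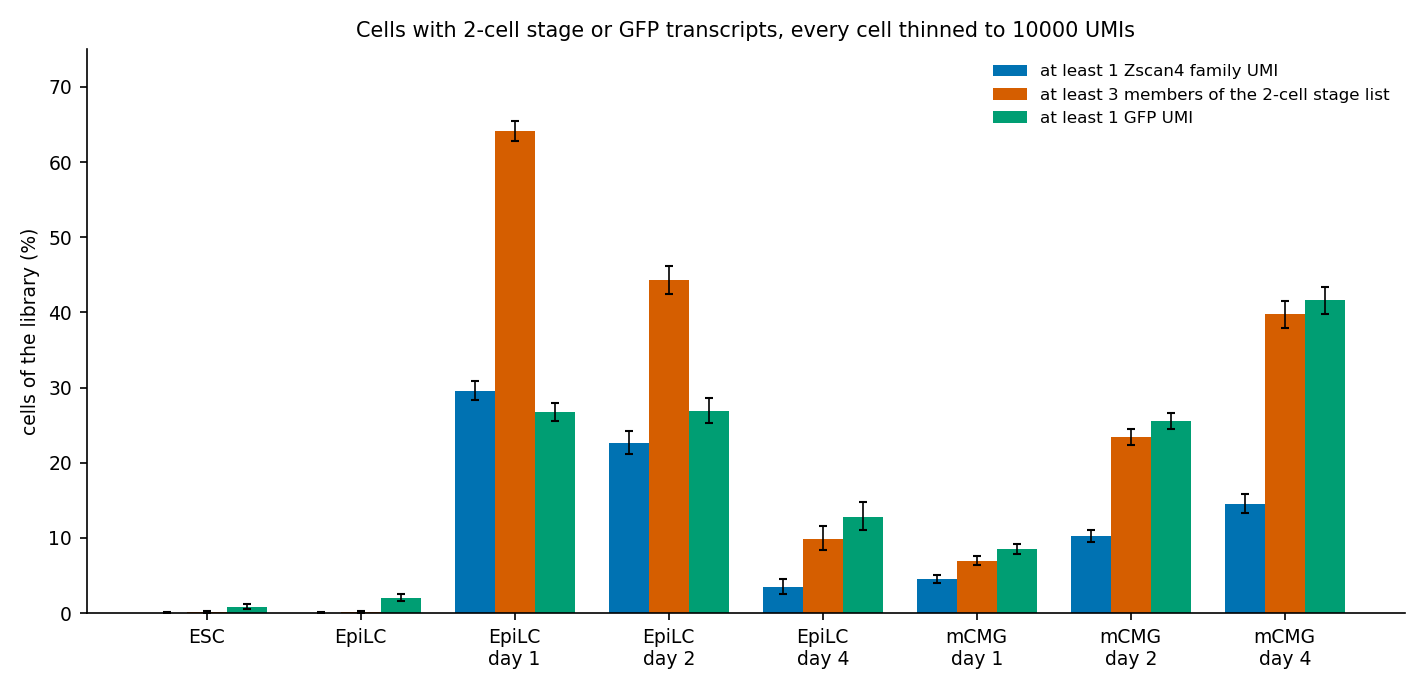
Share of cells in percent with a Zscan4 family UMI, with at least 3 genes of the 2-cell list, and with a GFP UMI, after thinning to 10000 UMIs, as bars for the 8 stem cell libraries with exact 95% binomial intervals. The Zscan4 share stood at 29.6% in induced EpiLC day 1 and 3.43% on day 4, and at 4.48% and 14.5% in mCMG.

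Which cells of induced EpiLC day 4 held the trophoblast RNA was read from clusters named by fixed marker genes. A trophoblast stem-like cluster held 113 of the 1319 day 4 cells (8.57%, 7.11 to 10.2) and 4 day 2 cells, and 0 cells of ESC, EpiLC or day 1. Because the cells were grouped on their expression, the levels describe the group and test nothing. They held 94.8% of the day 4 UMIs of Krt8, 98.2% of Plac1, 91.5% of Hand1, 95.7% of Cdkn1c and 80.7% of H19, against 9.89% of all UMIs. Krt8, an epithelial keratin, stood at 3026 CPM in these cells and 18.0 in the other day 4 cells. The trophoblast regulators Cdx2 (75 UMIs in these cells) stood at 12.4 and 0.417, Elf5 at 32.2 and 1.67, and Hand1 at 115 and 1.18. Of the same list, Eomes, a marker of the class that named the cluster, was not higher, at 7.11 and 10.4 CPM. Tead4 stood at 8.92 and 10.2, and Tfap2a at 1.16 and 2.30. Pluripotency genes lay lower in these cells, with Pou5f1 at 16.9 and 98.5 CPM, Nanog at 26.6 and 302 and Zfp42 at 186 and 1512. Gm8300 of the 2-cell stage stood at 10.1 and 102. The mCMG table gave no trophoblast-like cluster. Over 41 other clusterings, with other random seeds or rounding, the share ran from 5.99% to 8.72%, and the same 79 cells fell in the cluster in each, so the interval above understates its uncertainty.

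**Figure D3:**
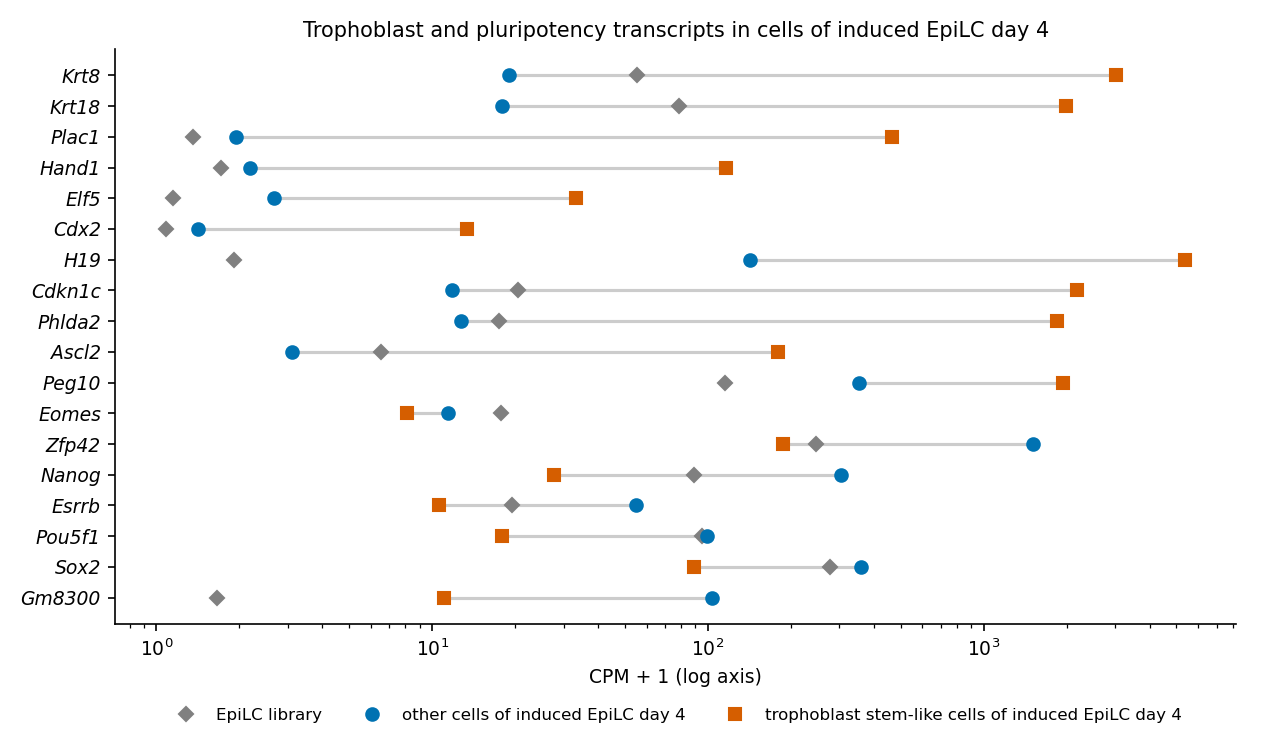
Levels of 18 genes in CPM plus 1 on a log axis, in the EpiLC library (grey diamonds), in trophoblast stem-like cells of induced EpiLC day 4 (orange squares) and in the other day 4 cells (blue circles). Krt8 stood at 3026 CPM in the trophoblast stem-like cells and 18.0 in the other day 4 cells, and Nanog at 26.6 and 302.

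Which cell classes the fetus, placenta and yolk sac held was read the same way. The fetus was mostly neuron-like, mesenchyme-like and chondrocyte-like cells, the placenta held spongiotrophoblast-like and erythroid-like cells, and the yolk sac held visceral endoderm-like or hepatocyte-like, erythroid-like and macrophage-like cells. Neuron-like cells made up 28.5% of the fetus (27.3 to 29.8), mesenchyme-like cells 24.0%, chondrocyte-like cells 12.2% and neural progenitor-like cells 6.66%, with 19.4% of cells unnamed. Sox11, a factor of young neurons, stood at 2217 CPM in the fetus, 0.395 in the placenta and 0.923 in the yolk sac. Spongiotrophoblast-like cells made up 38.3% of the placenta (34.7 to 42.0) and erythroid-like cells 15.8%, with 42.6% unnamed, and the spongiotrophoblast genes Tpbpa (19677 CPM) and Tpbpb (5470 CPM) and the placental prolactin Prl3b1 (2377 CPM) were abundant in that library. Visceral endoderm-like or hepatocyte-like cells, whose markers overlap, made up 54.4% of the yolk sac (52.6 to 56.2), erythroid-like cells 23.2% and macrophage-like cells 3.49%, and the secreted proteins Afp (10895 CPM, against 5.93 in the fetus) and Apoa1 (3254 CPM) were abundant. The shares moved with the clustering itself. Over 41 other clusterings the neuron-like share had a median of 27.0% (16.4% to 28.2%), the spongiotrophoblast-like share a median of 19.4% (19.2% to 42.9%) and the visceral endoderm-like or hepatocyte-like share a median of 41.2% (28.3% to 56.9%), so the last 2 shares given above lie well over their typical value. Under other settings the largest placental class was syncytiotrophoblast-like (31.7% at Leiden resolution 2, 31.8% with at least 1000 genes) or trophoblast giant cell-like (38.2% without Scrublet calls), and the largest fetal class mesenchyme-like (28.4% at resolution 0.5, 30.3% without Scrublet calls). Genes of the 2-cell stage summed to 14.9 CPM in the fetus, 14.4 in the placenta and 8.45 in the yolk sac over 5 listed genes.

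**Figure D4:**
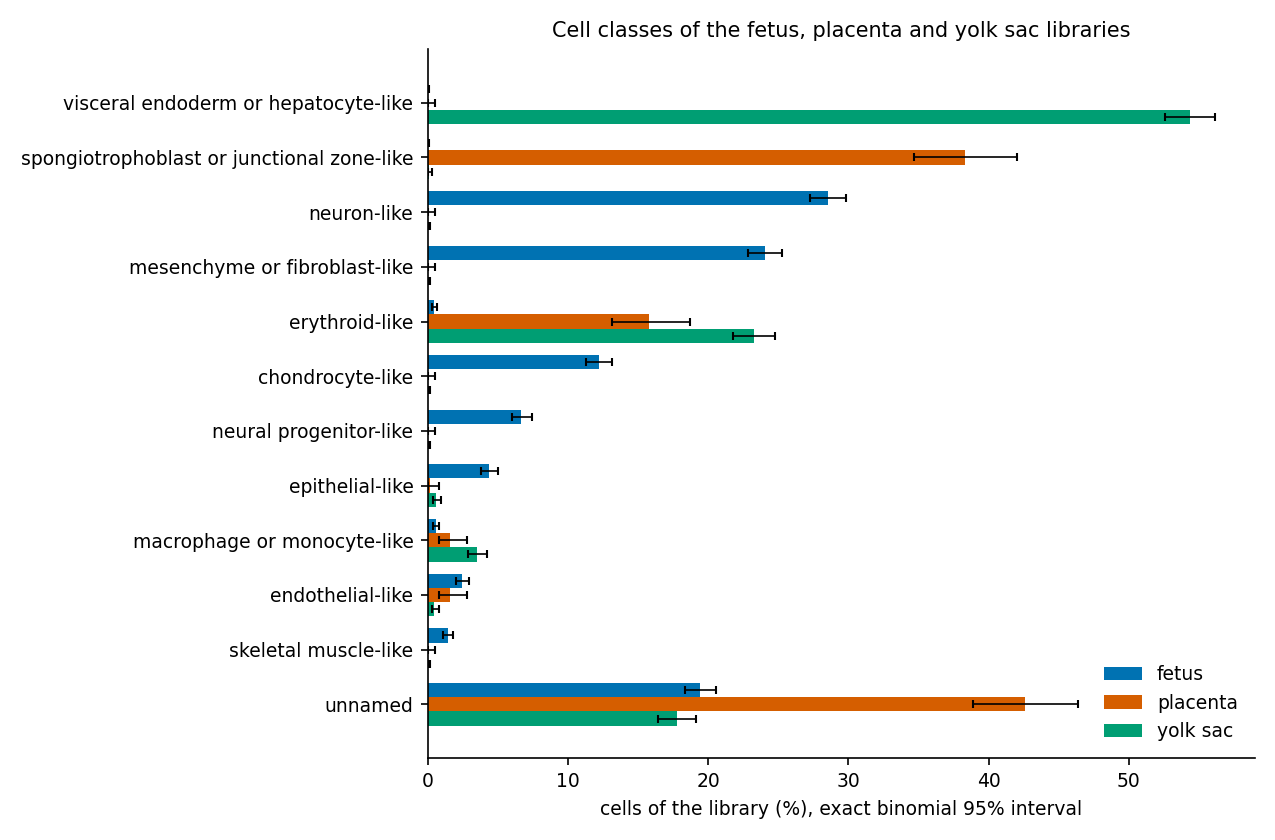
Share of cells in percent for each named class of fetus, placenta and yolk sac, as horizontal bars with exact 95% binomial intervals. Neuron-like cells made up 28.5% of the fetus, spongiotrophoblast-like cells 38.3% of the placenta, and visceral endoderm-like or hepatocyte-like cells 54.4% of the yolk sac.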

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

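The tests of library batch, of cells with a like number of UMIs, of a library set difference, of shared reads between near-identical copies and of EpiLC cells that were never induced were chosen only after the result was seen, and so was the measure of spread used for free RNA.

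Transcripts of the 2-cell stage took opposite courses from day 1 to day 4, falling short of day 1 in induced EpiLC and exceeding it in mCMG, and the difference was not tested because each group has 1 library. The median log2 fold of day 4 over day 1 was −3.03 in induced EpiLC and 0.94 in mCMG, a gap of 3.97. Library names number induced EpiLC day 1 and mCMG 9 to 12, and the other stem cell libraries 1 to 4. Day 4 against day 1 thus crosses these numbers in induced EpiLC and the deposited limits in both courses. At matched days, mCMG against induced EpiLC crosses the numbers on days 2 and 4, and on day 2 it crosses the deposited limits too. The split by number separated 7 genes, against up to 79 for another split into 4 and 4. The share of cells with a Zscan4 family UMI differed by −26.1 percentage points in induced EpiLC and 10.1 in mCMG (gap 36.2). For cells with at least 3 genes of the list the differences were −54.2 and 32.8 points (gap 87.0), and for cells with GFP −13.9 and 33.1 points (gap 47.0). In data outside the comparisons, the fetus library held 86 UMIs of a feature named GFP1, in 84 of 4877 cells (1.72%, exact 95% interval 1.38 to 2.13). Placenta held it in 3 of 697 cells (0.43%, 0.089 to 1.25) and yolk sac in 3 of 3039 (0.099%, 0.020 to 0.288). Scaled to library size it stood at 1.59 CPM in fetus (1.27 to 1.96), 0.237 in placenta (0.049 to 0.693) and 0.060 in yolk sac (0.012 to 0.176). Those fetal cells included 9 of 213 epithelial-like, 18 of 1392 neuron-like and 12 of 594 chondrocyte-like cells.

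The level of 2-cell transcripts in induced libraries against EpiLC was weighed against technical causes. A difference between library sets would leave few genes higher in induced EpiLC day 2, which shares the deposited limits of EpiLC, but 39 genes were at least 2-fold higher there, Gm8300 among them. Reads shared between near-identical copies would spare genes outside the multigene families, yet 7 of 8 such genes, including Zfp352 and Arg2, were higher. The 8 genes were chosen by name, and their number of copies was not checked. Free RNA spread evenly would give a variance of list genes per cell near the mean, and the lowest ratio among the 6 induced libraries was 6.23. Cells at 0 exceeded an even spread in each of the 6, from 4.70% against 0.123% in induced EpiLC day 1 and 14.9% against 0.47% in day 2 to 48.6% against 30.5% in mCMG day 1. The bound written beforehand was not met in any of the 6: most cells were not at 0, and the share with at least 3 genes was 0.49 to 0.78 times that of an even spread, not over 3 times. The values thus argue against evenly spread free RNA as the only source, while free RNA as part of the signal, the purification gate and a change of cell state with induction may each be involved.

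The trophoblast-like cells of induced EpiLC day 4 were weighed in the same way. Doublets would carry much of the RNA of their neighbours, but naive pluripotency genes such as Zfp42 stood at a median ratio of 0.161 to the other day 4 cells. Spongiotrophoblast-like placental cells carried over would bring Tpbpa and the prolactins, of which the highest ratio to the placenta library was 0.00224. This measure replaced the median ratio, 0, after the values were seen. An unnamed cluster with 252 of 697 placenta cells (36.2%) had Ldoc1 and Plac1, but no prolactin or Tpbpa, among its leading genes. Ldoc1 and Plac1 also lead the trophoblast-like cluster, so the measure cannot decide on carry-over of such cells. EpiLC cells that were never induced would hold Plac1, H19 and Hand1 at EpiLC levels, and the smallest log2 fold of those genes over EpiLC was 6.08. They would also hold Rhox6, Rhox9, Krt8 and Krt18 at EpiLC levels, and the folds were 2.63, 3.455, 5.78 and 4.65. The first 3 genes lead the cluster against all other cells, EpiLC included, and the others are markers that named it. High folds were therefore set by the grouping and cannot decide on this explanation. A trophoblast-like fate taken by some induced cells may explain them, as a hypothesis found and tested on the same cells.

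Genes that separate induced EpiLC day 1, mCMG day 1 and mCMG day 2 from the other 5 stem cell libraries numbered 108, of 7328 with at least 20 CPM, led by Id1, Slc7a5 and Pou5f1. The highest count among the other 55 splits was 75. A GC content bias would tie the difference to GC, but rho across genes was 0.0501 (Spearman; genes are not independent). If genes followed the number of UMIs per cell, cells of 20000 to 30000 UMIs from every library would not be separated, but 80 of the genes stayed separated in them; sequencing depth of a whole library was not tested. A library batch and the days and media cannot be told apart here, since both day 1 libraries lie in one set and both day 4 libraries in the other.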

How the results depend on the processing

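Of the settings here, leaving out trophoblast-like cells, genes that separate the library sets or multigene families, and other clustering seeds, were chosen only after the data were seen. Of 269 values of 25 list counts under alternatives, 253 stayed within 1.5 times the reported count and 16 moved; TMM, DESeq2 size factors, mean CPM per cell, no UMI minimum for list genes and leaving out the set genes moved 0 of the 25. Keeping all barcodes and the stricter cell filter (25 values each) were void for these counts, since neither changes the cells, and leaving out Scrublet calls removed at most 19 cells per stem cell library and 0 in mCMG, so it tests little. Without multigene families at most 8 genes of the 2-cell list remain, and counts with the full list follow in brackets. Those higher were then 7 (40) and 7 (39) in induced EpiLC days 1 and 2 against EpiLC, and 3 (22) and 3 (21) in day 4 against EpiLC and ESC. In mCMG days 2 and 4 against day 1 they were 1 (15) and 4 (22). In mCMG against induced EpiLC, 5 (28) were higher on day 4, while those lower on days 1 and 2 were 7 (38) and 4 (32). For day 4 against EpiLC and ESC, a minimum of 5 CPM gave 11 and 11, and a pseudocount of 0.1 gave 36 and 35, since the first measures fewer genes and the second shrinks low levels less. Without the trophoblast-like cells, trophoblast genes numbered 5 (of 13) against EpiLC and 9 (of 18) against ESC higher, and 4 (of 16) lower in mCMG, and folds reversed for Krt7 (−0.066), Krt8 (−1.54) and Cdkn1c (−0.79) against EpiLC and for Krt8 (0.87) and Ldoc1 (0.16) in mCMG day 4, as removing those cells must do for genes they hold. With the 79 cells found in each clustering removed instead, the counts were 7, 14 and 7, and Krt7 stood at 1.23. Zscan4 shares in percent on induced EpiLC days 1, 2 and 4 and mCMG days 1, 2 and 4 were 19.8, 16.2, 2.06, 2.68, 5.87 and 9.49 with at least 2 UMIs; 34.6, 37.8, 6.22, 5.91, 13.3 and 22.7 without thinning; and 13.0, 10.7, 1.14, 1.90, 4.39 and 5.58 at 1000 UMIs, as fewer or more UMIs per cell must give; of 18 other shares of stem cells 16 moved without thinning and 16 at 1000 UMIs. For neuron-like fetus, spongiotrophoblast-like placenta and visceral endoderm-like or hepatocyte-like yolk sac cells, the cause was not tested: Leiden resolution 0.5 gave 26.1 and 41.0 for fetus and yolk sac, resolution 2 gave 25.0, 19.4 and 39.3, at least 1000 genes and at most 10% mitochondrial gave 19.3 and 41.8 for placenta and yolk sac, leaving out Scrublet calls gave 26.4 and 41.7 for fetus and yolk sac, and 4000 variable genes gave 31.3, 42.9 and 62.1. Across other seeds the lowest shares were 16.4, 19.2 and 28.3, and 5.99 for trophoblast-like day 4 cells, and the highest that moved were 42.9 for placenta and 56.9 for yolk sac. Of 4017 other values of single genes 628 moved and 5 reversed. Depth limits genes at few UMIs, such as Fgf5 in ESC.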

Other observations

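The contrasts within libraries were added after other results had been seen, and 0 of the 3 tests set out here were chosen after their own result was seen: those of GFP, core pluripotency genes and numbers of genes per cell.

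Within each induced library, cells with at least 3 genes of the 2-cell list were set against cells with none. The share of cells with a GFP UMI was higher in the former by 38.4 percentage points on average (30.5 to 47.3), in 6 of 6 libraries. The exact two-sided sign-flip p was 0.0312, the smallest that 6 libraries allow, and 0.0938 after adjustment over 24 measures, which fails the correction. These libraries are days of the induced EpiLC and mCMG courses and not independent replicates, which the sign-flip test assumes. Its p-values here and below thus describe these libraries only. Fgf1, a growth factor, and Dcc, a netrin receptor, stood 4.61 to 6.04 and 4.43 to 5.77 higher on the log2 scale, and 75 genes outside the list were at least 2-fold higher in 6 of 6 libraries against 0 lower. The 75 include GFP, Zscan4-ps2, and Gm21818, Gm4971 and BC147527, which are among the leading genes of the 2-cell-like mCMG cluster. Such genes may follow the list genes that chose the cells, so part of the count restates that choice. Core pluripotency genes were lower by a small margin, with a mean of −0.12 (−0.19 to −0.03) in 6 of 6 libraries (exact p 0.0312, adjusted 0.0938), when the median of all genes was −0.05. BMP targets (0.60) and neuroectoderm genes (0.42) were higher in 6 of 6 libraries, and genes of S phase (−0.24) and chromatin regulators (−0.15) lower in 6 of 6, again without passing the correction. Genes of oxidative phosphorylation (−0.07) and G2M phase (−0.10) were also lower in 6 of 6 and failed the correction. The cells with list genes also had fewer UMIs before thinning and a higher median mitochondrial share in 6 of 6 libraries, for example 36991 against 48218 UMIs and 2.75% against 2.20% in induced EpiLC day 4, so cell quality was not held equal in these contrasts. Numbers of genes per cell at equal depth gave an exact p of 0.531, with fewer genes in 3 of 6 libraries.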
